A study of Mus musculus with 6 samples.

How the data were processed

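RNA was sequenced from mouse sperm of a transgenic C57BL/6 line, collected from the cauda epididymis and vas deferens. Per the labels' protocols, cells were passed through a mesh and washed, nuclei were freed by sonication and recovered by ultracentrifugation through sucrose and caesium chloride with detergent, and whole-sperm RNA was extracted in the same way without those steps after a visual check for other cell types. Extracts were treated with DNase and tested by RT-PCR for Prm2. The labels name 6 samples, which are 2 runs of each of 3 preparations: nuclei 1, nuclei 2 and whole sperm. The runs were treated as combined in 1 column per preparation, so the comparison is 2 nuclei libraries against 1 whole-sperm library. The labels do not tie the preparations to animals. P-values of single genes rest on the spread between the 2 nuclei preparations, pooled over genes, which may be technical.

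The count columns are whole numbers of reads per gene or region, deposited by the authors without normalization. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.12, Cufflinks 2.1.1, SAMtools 0.1.19, bedtools, HTSeq and DESeq2 were used with build mm10; the role and order of each are not given in the sources used here. The strand setting of the counting is not given either, so reads of a gene and of an antisense partner cannot be told apart. The deposited RPKM table holds 1 column per preparation, and RPKM per count, relative to whole sperm, varied between genes with an SD of 0.417 (nuclei 1) and 0.436 (nuclei 2) on the log2 scale over 6602 and 6600 genes with at least 20 counts, so the 2 tables were not made from 1 count per gene by a single factor per library. The adjusted whole-sperm column deposited by the authors was handled as a score, since every one of its 25610 gene and region rows equalled the whole-sperm count less the mean of the 2 nuclei counts, never under 0, within a tolerance of 0.5. Region coordinates come from the authors' deposited list. ERCC spike-ins, synthetic RNAs of known concentration, stayed out of library sizes and tests. The amount and mix added to each library are not given in the sources used here. Spike-in scaling used the 23 spike-ins shared by every count table and assumes that their amount was the same. The whole-sperm table also held reads outside features (5896320, 34.4% of the file total) and ambiguous reads (336963, 1.97%), which were left out too.

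The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. It has 1 residual degree of freedom, and the lone whole-sperm library is assumed to vary like the nuclei libraries. Of 25610 rows, 16720 were tested, of which 14397 were annotated genes and 2323 were assembled regions. Fold changes are nuclei over whole sperm, and levels are TMM-normalised CPM, given for nuclei as mean ± SD of n = 2. The standard error of a log2 fold change was derived from the F statistic. The prior degrees of freedom were infinite, so p-values and standard errors rest on a spread pooled over genes. They do not measure a gene's own spread between the nuclei libraries. For a group at 0, the fold was computed against a floor of 3 counts per library. Shares of counts have exact Clopper-Pearson 95% intervals; intervals and floors cover counting error only, since PCR copies were not identified.

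Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and, beside it, an estimated one. At the preset, p-values set a list's genes against the other genes and do not measure the spread between preparations. The estimate rests on 1 residual degree of freedom. It called no list, also where the estimate was below the preset (epididymal list -0.022). A call lost there does not weigh against a list, and a call at the preset does not settle it. Of 23 lists, 18 had the 5 or more tested members required. Each list's median was also placed among 10000 random lists matched on mean expression. RPKM values were tested with limma on log2(RPKM + 0.1). Gene positions, transcript lengths and overlaps come from GENCODE vM21, whose assembly matches build mm10; 21592 of the 23229 gene symbols were found in it.

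The groups, tests, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, in each direction, the 10 largest fold changes with adjusted p under 0.05, a mean of at least 20 CPM and both nuclei libraries on one side of whole sperm. It also took the 10 genes with most counts in each fraction, up to 4 members of each list with the highest mean, and Prm2. Genes named outside the rule are said to be so. Alternatives were DESeq2 size factors, library size alone, spike-in scaling, leaving out the 10 most abundant features, no filter, a mean of at least 10 CPM, DESeq2 1.42.0, the adjusted column, the limma settings on RPKM, and each nuclei library alone. Counts were simulated for the 16720 features in 2 against 1 libraries (5 simulations), with changed genes taken from those with a mean of at least 20 CPM. On these, edgeR recovered 14.4% of genes changed 8-fold and 84.2% of genes changed 64-fold. It called 0.0623% of unchanged genes, while limma on log values recovered 0% at both sizes. Recovery at lower expression was not simulated. Camera called the planted list in 5 of 5 simulations and the unchanged list in 0 of 5, each of 60 genes, at an unadjusted p under 0.05. Genes were simulated independently, so false calls from correlated genes were not tested.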

Results

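The series compared RNA of mouse sperm nuclei with RNA of whole sperm, to learn how transcripts are divided between the nucleus and the rest of the cell. Gene and region counts came to 5487306 in nuclei 1, 6648848 in nuclei 2 and 8316345 in whole sperm. Annotated genes with a count numbered 13897, 12259 and 14630 in that order. Whole sperm had no replicate, so its values carry no spread of their own.

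Ribosomal RNA led every library. Rn45s, the ribosomal RNA precursor, took 42.5% of counts in nuclei 1, 33.3% in nuclei 2 and 43.4% in whole sperm, and Lars2, a mitochondrial leucyl-tRNA synthetase gene, took 6.37%, 4.27% and 6.16%. Both counts are uncertain, since Rn45s is repeated in the genome and reads shared between it and Lars2 cannot be excluded. After these, Eif4g1, a translation initiation factor gene, was the most abundant gene in nuclei at 9351 ± 4299 CPM (SD, n = 2), against 3168 CPM in whole sperm (log2 1.56, edgeR adjusted p = 0.909). In whole sperm the next annotated genes were Crisp1, a secreted epididymal protein gene, at 6452 CPM, the long noncoding RNA Malat1 at 6200 CPM, and Akr1b7, a vas deferens reductase gene, at 5560 CPM, while the assembled region TCONS_00042770, in the mitochondrial 12S ribosomal RNA gene, stood above them at 12446 CPM. Prm2, the protamine assayed by RT-PCR in every extract, was at 512 ± 114 CPM in nuclei (n = 2) and 319 CPM in whole sperm (log2 0.68, adjusted p = 0.909).

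The first comparison asked which genes were higher in nuclei. Fam122c (build mm10, X:53273424-53331185) had 330 and 332 counts in nuclei and 0 in whole sperm, at least 163-fold higher. The X-linked 4932411N23Rik rose 42.8-fold (log2 5.41 ± 1.21 SE, adjusted p = 0.0136), but at 196 CPM in nuclei 1 and 21.4 in nuclei 2, against 2.54 in whole sperm; its log2 difference was 6.02 from nuclei 1 alone and 2.85 from nuclei 2 alone. Wdr37, a WD-repeat protein gene, was at 1026 and 366 CPM in nuclei and 49.8 CPM in whole sperm (log2 3.80 ± 0.907, adjusted p = 0.0241; 2.87 from nuclei 2 alone). Usp17la, a deubiquitinase gene, rose by log2 3.88 (2.85 from nuclei 2 alone), to 560 and 186 CPM from 25.3 CPM (adjusted p = 0.0205), a value that is uncertain because the gene has near-identical copies. These 4 of 14397 genes were all that edgeR placed higher, with 448 at an unadjusted p under 0.05.

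In the other direction, 16 genes fell in nuclei. Gm20594 (6:79817916-79818364), a gene that resembles mitochondrial 16S ribosomal RNA and is uncertain for that reason, fell from 1380 CPM in whole sperm to 43.1 ± 36.2 CPM in nuclei (SD, n = 2; log2 -5.00 ± 0.755 SE, edgeR adjusted p = 5.84e-07), with a log2 difference of -4.32 from nuclei 1 alone and -6.26 from nuclei 2 alone. The membrane haem-binding protein gene Pgrmc1 was at 361 CPM in whole sperm and 15.2 ± 1.16 CPM in nuclei (log2 -4.57, adjusted p = 2.36e-05). Crisp1 (17:40293758-40319207) was at 6452 CPM in whole sperm and 507 ± 26.5 CPM in nuclei, 12.7-fold lower (adjusted p = 0.0241). The lysosomal membrane gene Lamp2, the endoplasmic reticulum reductase gene Dnajc10, the lipid enzyme genes Pla2g4a, Sgpp1 and Acsl4, the ubiquitin ligase gene Rnf128 and the tight junction gene Cldn8 had log2 fold changes of -4.22 to -3.30; Rnf128 was uneven, at 14.5 and 1.35 CPM in the nuclei libraries (log2 -3.30 from nuclei 1 alone and -6.32 from nuclei 2 alone), and Cldn8 had -4.44 from nuclei 2 alone. Zkscan16, Spink10, Hpgd, Glb1l2, Abcg2 and Serinc3 also passed, outside the naming rule and named after their values were seen; Zkscan16 had 0, 0 and 491 counts, at least 111-fold lower in nuclei. At an unadjusted p under 0.05, 335 genes were lower. Of the 14397 genes tested, a share of about 0.05 would pass that threshold without any difference. The 448 higher and 335 lower genes are therefore not counted as differences. Both nuclei libraries lay on the same side of whole sperm for all 20 genes. No gene passed in the count test restricted to a mean of at least 10 CPM (346 higher and 269 lower at an unadjusted p under 0.05), while DESeq2 called 198 higher and 38 lower and spike-in scaling 1 and 527.

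**Figure D1:**
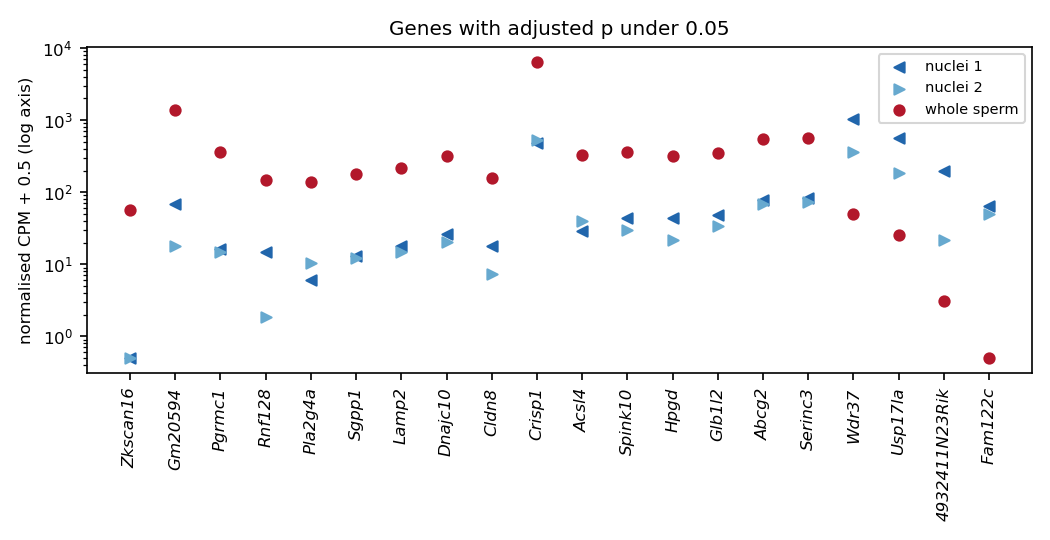
Normalised CPM plus 0.5 on a log axis for the 20 genes with edgeR adjusted p under 0.05, with 1 point per library. Crisp1 stands at 6452 CPM in whole sperm and at 488 and 525 CPM in the nuclei libraries.

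Genes of the epididymal epithelium were much scarcer in nuclei. Of 42 tested members of the epididymal secretory list, 36 lay below 0 (median log2 -1.64, camera adjusted p = 4.12e-13; adjusted p = 0.688 with an estimated correlation). Only Crisp1 fell over all genes; adjusted over the list alone, 7 members fell. The list's share of counts was 0.252% (95% interval 0.247 to 0.256) in nuclei 1, 0.281% (0.277 to 0.285) in nuclei 2 and 1.42% (1.41 to 1.43) in whole sperm. Serpina1f, a serine protease inhibitor gene, was at 327 ± 135 CPM in nuclei and 1562 CPM in whole sperm (edgeR adjusted p = 0.273), Spink8 at 194 ± 44.5 and 811 CPM (adjusted p = 0.346), and Cd52 at 714 ± 50.7 and 1757 CPM (adjusted p = 0.909). In the vas deferens and accessory gland list, too small for the list test with 4 tested members, Akr1b7 was at 826 ± 13.4 and 5560 CPM (log2 -2.75, edgeR adjusted p = 0.228), and it was the 1 member that fell when adjusted over the list alone.

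Markers of epithelial cells were lower in nuclei too: 14 of 19 lay below 0 (median log2 -1.36, camera adjusted p = 0.00376; adjusted p = 0.688 with an estimated correlation). No member fell over all genes and 2 did adjusted over the list alone, the cell adhesion genes Epcam (9.06 ± 6.06 and 107 CPM) and Cdh1 (19.7 ± 0.922 and 122 CPM). From nuclei 1 alone the list's median was -1.06, and from nuclei 2 alone -2.50. Leukocyte markers had a median of -1.76 (18 tested, camera adjusted p = 0.197) and smooth muscle and stroma markers -1.32 (17 tested, adjusted p = 0.427). Among random lists these medians stood at percentiles 1.11 and 1.9, and that of epithelial markers at 0.49. By share of counts in nuclei 1, nuclei 2 and whole sperm, leukocyte markers took 0.0131%, 0.00600% and 0.0138%. Smooth muscle and stroma markers took 0.0315%, 0.0426% and 0.0316%. Of 3 tested Sertoli and Leydig cell markers none was called, and the median was -2.24, or -1.21 from nuclei 1 alone and -2.39 from nuclei 2 alone. No erythrocyte gene was tested, and that list had 0, 4 and 3 counts in nuclei 1, nuclei 2 and whole sperm.

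Transcripts of oxidative phosphorylation, ribosomal protein and vesicle genes lay lower in nuclei as well. Of 78 nuclear-encoded oxidative phosphorylation genes, 61 were below 0 (median log2 -1.57, camera adjusted p = 2.91e-06; adjusted p = 0.688 with an estimated correlation). None fell over all genes and 2 did adjusted over the list alone, Cox6c (11, 20 and 771 counts) and Ndufc1 (0, 4 and 422 counts), both named after their values were seen. Of 77 ribosomal protein genes, 51 were below 0 (median -0.66, adjusted p = 0.00376; adjusted p = 0.688 with an estimated correlation), among them Rpl7 at 114 ± 49.4 and 316 CPM. None changed over all genes, and adjusted over the list alone 1 rose, Rpl27, which is uncertain because of its processed pseudogenes (2193, 312 and 225 counts). Of 39 extracellular vesicle genes, 26 were below 0 (median -0.74, adjusted p = 0.00605; adjusted p = 0.722 with an estimated correlation), and Lamp2 was the 1 that fell, over all genes and adjusted over the list alone. Translation factors were not called (36 tested, median -0.28, camera adjusted p = 0.138), though their median stood at percentile 1.67 of random lists. They took 0.996%, 1.50% and 0.857% of counts in nuclei 1, nuclei 2 and whole sperm. Eef1a1, elongation factor 1 alpha, was at 689 ± 240 and 2174 CPM (edgeR adjusted p = 0.71). Eif4g1 was at 9351 ± 4299 and 3168 CPM and Eef1g at 535 ± 524 and 102 CPM (edgeR adjusted p = 0.364).

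The nuclear condensation list, protamines and transition proteins that pack spermatid DNA, lay higher in nuclei for all 7 tested members (median log2 0.92, camera adjusted p = 0.00227; adjusted p = 0.688 with an estimated correlation). Tnp2 was at 1225 ± 272 and 304 CPM, Tnp1 at 1126 ± 459 and 574 CPM, and Prm1 at 456 ± 233 and 231 CPM. No member changed over all genes or adjusted over the list alone. The median stood at the 64.8th percentile of random lists of the same expression. With spike-in scaling the list was no longer called, and its median was -0.52 while the median of all features was -1.16. From nuclei 2 alone it was 0.48. The list took 0.359%, 0.301% and 0.153% of counts in nuclei 1, nuclei 2 and whole sperm.

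Other germ cell lists were not called. Sperm tail and midpiece genes had a median of 0.42 (29 tested, camera adjusted p = 0.197; 0.53 from nuclei 1 alone and 0.08 from nuclei 2 alone), spermatogonia and spermatocyte genes 0.66 (30 tested, adjusted p = 0.2; 0.05 and 0.50) and chromatin regulators -0.25 (42 tested, adjusted p = 0.939; -0.65 and -0.04), among which Chd5, a chromatin remodeller gene, was at 2191 ± 1252 and 596 CPM. Glycolysis isoforms had a median of -0.04 but a mean of 0.38 and an upward test (15 tested, adjusted p = 0.427). Acrosome and sperm surface genes had a median of -0.59 and a mean of -0.29 beside an upward test (33 tested, adjusted p = 0.939); Acrbp, an acrosomal binding protein gene, was at 151 ± 10.3 and 38.2 CPM. Replication-dependent histones had a median of -0.13, a mean of 0.10 and a downward test (29 tested, adjusted p = 0.683), with 0.21 from nuclei 1 alone and -0.25 from nuclei 2 alone. The multicopy sex-chromosome list had 3 tested members, too few for the list test, and a median of 4.52, or 2.28 from nuclei 1 alone and 1.76 from nuclei 2 alone.

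No list of noncoding RNAs was called. Among 18 long noncoding RNAs of nuclear location the median was 0.02 and the mean 0.26, while the test pointed down (camera adjusted p = 0.939). Malat1 was at 1548 ± 18.4 CPM in nuclei and 6200 CPM in whole sperm (4.01-fold lower, edgeR adjusted p = 0.666), whereas Kcnq1ot1, an imprinted antisense RNA whose counts cannot be told from its sense partner, was at 998 ± 667 and 300 CPM and Snhg11 at 410 ± 243 and 93.7 CPM. Short nuclear and nucleolar RNAs had a median of -0.62 and a mean of -0.06 (33 tested, camera adjusted p = 0.393), and none changed over all genes. The nucleolar RNA gene Snora81 was the 1 that fell adjusted over the list alone (67.4 ± 33.8 and 404 CPM). MicroRNA genes had a median of -2.16, or -1.76 with genes at 0 set to their bound (20 tested, adjusted p = 0.427). The tables held no row named as a mitochondrially encoded gene.

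**Figure D2:**
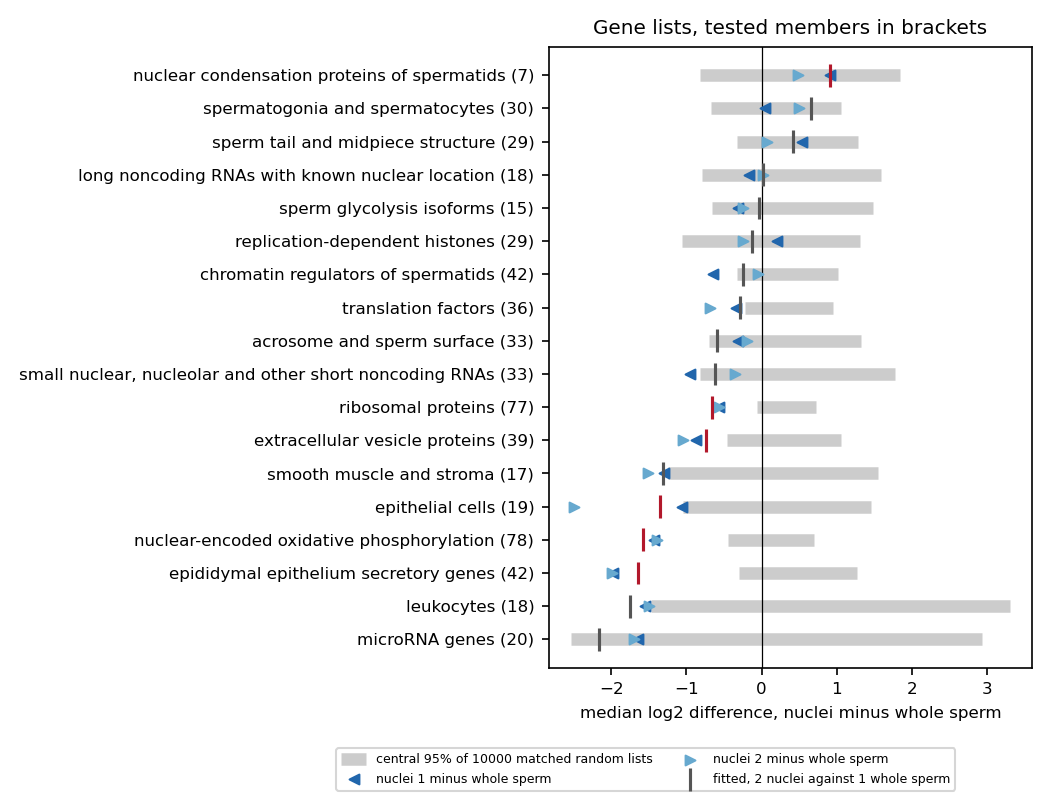
Median log2 difference of each tested gene list, with the fitted value as a bar (red where camera's adjusted p at the preset correlation was under 0.05), each nuclei library against whole sperm as triangles (log2 of CPM plus 0.5) and the central 95% of 10000 expression-matched random lists in grey. The epididymal secretory list lies at -1.64 and the nuclear condensation list at 0.92, the latter within its grey range and at -0.52 with spike-in scaling.

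The 2 nuclei preparations differed widely. Across 19432 features with a count, log2(CPM + 1) gave Pearson r = 0.663 and Spearman rho = 0.563, with an SD of the log2 difference of 1.92; these are correlations across genes, which are not independent replicates. Over the same features r was 0.616 between nuclei 1 and whole sperm and 0.675 between nuclei 2 and whole sperm, pairs set after seeing the data. With features of at least 10 CPM on average in the pair compared, r was 0.487 between the nuclei libraries (7077 features) and 0.387 and 0.372 between whole sperm and nuclei 1 and nuclei 2 (7694 and 7537 features). On the 7077 features chosen by the nuclei mean, whole sperm gave 0.586 and 0.619 with nuclei 1 and nuclei 2, so the order of the pairs depends on the filter. Of the 7077 features, 368 (5.20%) had no count in 1 of the nuclei libraries. The common biological coefficient of variation was 1.30.

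**Figure D3:**
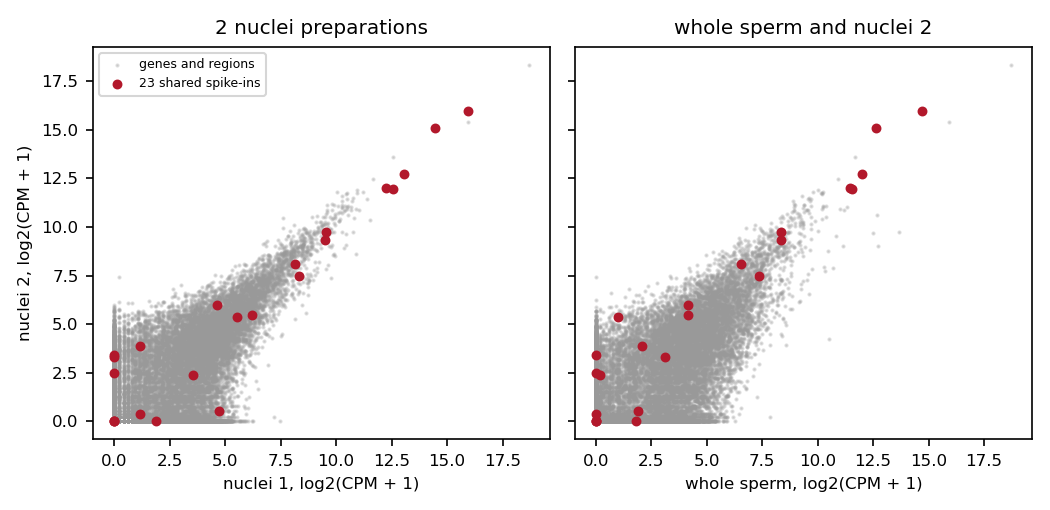
Each point is a gene or region (grey) or a spike-in present in every count table (red), as log2(CPM + 1) in nuclei 1 and nuclei 2 (left) and in whole sperm and nuclei 2 (right). Points at 0 on 1 axis have no count in that library.

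The deposited adjustment kept 40.8% of the whole-sperm counts over all rows. The nuclear condensation list kept 39 of 12715 counts (0.307%), the spermatogonia and spermatocyte list 21.3%, the tail and midpiece list 25.5% and the acrosome list 38.0%, whereas replication-dependent histones kept 62.4%, the epididymal list 86.4%, the vas deferens list 89.8% and the multicopy sex-chromosome list 50 of 53 counts. Of 15602 rows with a count, 5313 (34.1%) were set to 0, and the median ratio of adjusted to unadjusted counts was 0.533 over 11913 rows with at least 20 counts. Since the nuclei counts enter the adjusted column, setting it against nuclei is circular: that fit called 2571 genes higher and 38 lower, with all 20 genes kept.

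The authors listed 2381 assembled transcript regions of 266 to 65607 bases (median 336). Of these, 717 (30.1%) overlapped an annotated gene by at least 1 base, 368 touched an exon and 1664 lay outside genes. In the test, 7 of 2323 regions were higher in nuclei and none lower (183 and 11 at an unadjusted p under 0.05; DESeq2 called 6 higher and 1 lower, spike-in scaling 3 and 18, a mean of at least 10 CPM 0 and 0, and limma on RPKM 0 and 0). TCONS_00042396 (9:19884500-19885009), which overlaps an exon of the olfactory receptor gene Olfr862 and was named after its values were seen, had 205 and 495 counts in nuclei and 0 in whole sperm, at least 164-fold higher (edgeR adjusted p = 0.00172). Of the 7 regions, 3 had at most 1 count in 1 of the nuclei libraries. A count was present for 2056 regions in nuclei 1, 1304 in nuclei 2 and 972 in whole sperm.

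In the RPKM table, limma on log2(RPKM + 0.1) called 0 of 17430 genes, with 274 higher and 2245 lower at an unadjusted p under 0.05. The simulated limma test recovered no changed gene either, but it used log2(CPM + 0.1) of simulated counts and not RPKM. All 20 genes called by edgeR kept their direction in RPKM.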

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

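Results were taken up here because signal lay in data outside the comparisons. The whole-sperm table held 5896320 reads outside any feature and 336963 ambiguous reads, with no such rows in the nuclei tables. It also held 2206285 counts for 69 spike-ins that the nuclei count tables lack. No group had the 4 samples that a search for outlying samples needs. The tests of counting error, spike-ins, transcript length, scaling, epithelial markers, genomic DNA, capture of regions and other splits were chosen after the results they bear on, or values close to them, had been seen.

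The nuclei libraries agreed poorly (SD of the log2 ratio 3.81 for features of 3 to 1000 counts), and counting alone would give 0.454, which argues against sequencing depth. Spike-ins of that abundance spread by 4.38 (95% interval 3.06 to 7.69, n = 11), beyond the 0.434 that counting alone gives them. Genes at the same counts spread by 3.67, within that interval, as few molecules being captured in library preparation would give. The interval is so wide at n = 11 that genes could hardly have spread beyond it, so this comparison cannot decide for capture. The mix added to nuclei 2 is not given. In RPKM, log2 ratios of nuclei 2 to whole sperm had an SD of 1.62 for 38 spike-ins outside this comparison (0.396 in nuclei 1). For the 10 shared spike-ins over 10 RPKM in whole sperm, the SD was 0.753 (0.392 in nuclei 1). Of the 11 spike-ins above, only ERCC-00148 is among these 10, so that SD says little about the 11. The 9 shared spike-ins of at least 1000 counts spread by 0.432 between the nuclei libraries. Whether the shared spike-ins would differ between mixes is not given in the sources used here, so this cannot decide on a mix difference. For the 11 of 3 to 1000 counts the mix was not tested. At 1000 counts or more the 9 spike-ins spread by 0.432 (0.292 to 0.829) against 0.832 for genes, which alone would argue against capture, but those genes had lower counts than the spike-ins; at the spike-ins' counts, a comparison added once the first had been seen, genes spread by 0.699, so capture and a difference between the preparations cannot be told apart there. A difference between animals stays open and untested.

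Of the 5 lists lower in nuclei, none had a median above percentile 1.31 of lists matched on transcript length and abundance, which argues against length. Scaling moves the log2 differences of most features about alike, so it largely leaves a list's median in its place among other genes. The camera calls did depend on scaling: spike-in scaling gave 7 lists lower and 0 higher, against 5 and 1 in the main test. A lower amount and scaling of the libraries cannot be told apart. The medians stayed below 0 under the other scalings (closest -0.58), but none of these moved features up by more than 0.0817. Epithelial cells carried over into whole sperm, despite the mesh and the visual check, could bring the epididymal transcripts. The epithelial list had a median of -1.36, with Epcam at 107 CPM and Cdh1 at 122 CPM in whole sperm. Its call was lost with an estimated correlation (camera adjusted p = 0.688), but no list was called at that setting, so it cannot decide. Removal of tails, cytoplasm and attached vesicles with the fractionation, which the design names, would lower the same lists, so the 2 cannot be told apart with 1 whole-sperm library.

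For the assembled regions higher in nuclei, genomic DNA and RNA cannot be told apart. The 1398 olfactory and vomeronasal receptor genes had 0.115 and 0.0959 CPM per kilobase in nuclei and 0.0293 in whole sperm. A background of DNA would give that direction. But the 3242 and 3277 counts in nuclei 1 and nuclei 2 lay in 161 and 110 of 1409 genes, so they were not evenly spread. PCR copies were not identified, so this unevenness cannot decide. Whether these genes are silent in male germ cells was not tested. The at least 97.1 CPM per kilobase of the 7 called regions excludes nothing, since they were selected for their counts. Regions of 3 to 1000 counts were absent from 1 nuclei library in 53.3% of cases (51.3 to 55.4), against 20.3% of genes of the same counts. This cannot decide for or against capture as the cause. Regions (median 336 bases) and genes were matched on counts but not on length, and regions were chosen by assembly from reads. Assembly of regions from the reads of single libraries stays open, since the libraries used for it are not given in the sources used here.

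The labelled split called 20 genes, and the highest of the other 2 splits of the 3 libraries called 1; with 1 of 3 splits as large, the design allows no share under 0.05.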

How the results depend on the processing

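Scalings of the lists other than DESeq2 size factors, lists with 1 nuclei library left out, shares without Rn45s and Lars2, and single-gene alternatives were chosen after seeing the data. The 20 genes kept their direction under each alternative that tested them (Crisp1 is removed with the most abundant features). DESeq2 size factors kept all 20 calls and no filter 18. Of the named genes and regions without a call in the main test, the DESeq2 test called 14, and 8 stayed without a call. Malat1, Akr1b7, Serpina1f, Spink8 and Tnp2 were among the 14. Higher and lower genes numbered 2 and 13 with library size alone, 1 and 527 with spike-in scaling, 4 and 11 without the 10 most abundant features (3 and 11 shared; Wdr37, Cldn8, Glb1l2, Abcg2 and Serinc3 lost their calls), 0 and 0 with a mean of at least 10 CPM, 2571 and 38 with the adjusted column, 198 and 38 with DESeq2 (2 and 10 shared, 2 and 6 without an adjusted p), and 0 and 0 in all 3 limma settings. At a mean of at least 10 CPM the prior degrees of freedom were 7.25 (infinite in the main test) and the common biological coefficient of variation 0.825 (1.30 in the main test); the causes of these changes in calls were not tested. Spike-in scaling assumes the same amount of the shared spike-ins in each library. It moved the median of all features by -1.42 (log2) and the adjusted column moved it by 1.22, so directions hold relative to these shifts. Reversed values were, with spike-in scaling, the condensation list (-0.52), Prm1 (-0.44), Prm2 (-0.75) and Tnp1 (-0.46), and with the adjusted column ribosomal proteins (0.55), vesicle proteins (0.53), Rn45s (1.78) and Lars2 (1.73). Lists higher and lower numbered 0 and 7 with spike-in scaling, 4 and 4 with the adjusted column, and 0 and 0 with an estimated correlation. Agreement of the nuclei libraries was 0.487 at 10 CPM and 0.549 in RPKM. Leaving out 1 nuclei library gave the condensation list 0.48 to 0.91, the epididymal list -1.99 to -1.98, oxidative phosphorylation -1.43 to -1.40, ribosomal proteins -0.57 to -0.56, vesicle proteins -1.05 to -0.88 and epithelial cells -2.50 to -1.06. With Rn45s and Lars2 left out of the totals, the epididymal share was 0.492%, 0.450% and 2.82% in nuclei 1, nuclei 2 and whole sperm. Requiring 0.5 of a region to lie in a gene gave 28.3% overlapping. No paired analysis was possible because whole sperm has 1 preparation and shares 1 replicate number with nuclei. With 1 residual degree of freedom, the simulated recovery of 14.4% at 8-fold, for genes of at least 20 CPM, limits what a missing call shows.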

Other observations

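Mitochondrial ribosomal RNA took a smaller share of counts in both nuclei libraries than in whole sperm. The assembled region TCONS_00042770 (M:187-456) lies in mt-Rnr1, the mitochondrial 12S ribosomal RNA gene, and had 9395, 5717 and 107760 counts in nuclei 1, nuclei 2 and whole sperm (log2 -3.23 ± 0.993 SE, edgeR adjusted p = 0.224). A second mitochondrial region at 15912-16177 had 0, 0 and 261 counts. Together the mitochondrial regions held 0.171% (95% interval 0.168 to 0.175), 0.0860% (0.0838 to 0.0882) and 1.30% (1.29 to 1.31) of counts. Both regions were chosen after their values were seen.

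Olfactory and vomeronasal receptor genes, chosen after seeing the data, took 0.0591% (0.0571 to 0.0612), 0.0493% (0.0476 to 0.0510) and 0.0151% (0.0143 to 0.0159) of counts in nuclei 1, nuclei 2 and whole sperm, with 161, 110 and 55 of the 1409 genes counted. The ratio of Rn45s to Lars2 counts was 6.66, 7.79 and 7.05 in the same order. In the RPKM table, 38 spike-ins outside the count tables of the nuclei had log2 ratios to whole sperm with an SD of 0.396 in nuclei 1 and 1.62 in nuclei 2; the mix added to each library is not given, and a different mix in nuclei 2 would widen its ratios.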
